A study of Mus musculus with 18 samples.

How the data were processed

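The values used were those deposited by the authors, 1 table of 48440 genes and 18 libraries in log2 FPKM. Per the labels, the libraries were made by the SMART-seq2 method with Nextera XT tags and read from both ends over 51 bases. Per the submitters' processing notes, reads were aligned with STAR 2.3 to the GRCm38 (mm10) assembly, counted with featureCounts 1.5 and turned into log2 FPKM with edgeR. Nothing was realigned here. The labels mention an ERCC spike-in, but the table holds 0 such genes, so it was not used here.

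The deposited values were turned back into reads by solving for the small count added before the logarithm, which averages 0.25 and scales with library size. Whole reads, within a tolerance of 0.01, came out for 48439 genes (99.998%) and 20460 genes had no read in any library. Odd read counts made up 41.54 to 44.59% of values per library, so the mates of a pair appear to have been counted separately and a count of 2 may be 1 fragment. The 95% intervals on reads do not allow for this. On simulated data of the same form, 100% of 48439 genes returned their exact reads. The reads served for depth, for ratios and for floors, and the tests used the deposited log2 FPKM.

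Genes with log2 FPKM of at least 0 in at least 3 of the 18 libraries were kept, which left 13738. A linear model with 6 group means was fitted in R 4.3.3 with limma 3.58.1, with a variance trend over expression level. The comparisons were infected against uninfected in each organ, the 3 differences of those effects between organs, and the 3 pairs of uninfected organs. The limit was a Benjamini-Hochberg adjusted p of 0.05, and for the pairs of organs also a log2 difference of at least 1. The 38 gene lists were tested with camera at a preset correlation of 0.01 between genes, and again with an estimated correlation and with fry. Counts within a list are given as adjusted over all genes and as adjusted over the list alone. The groups, lists, filter and tests of genes and lists were fixed before the data were examined, as were the alternatives other than those named as added in the closing section. The tests of other explanations were chosen later where that section says so.

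Per direction the genes named by rule were the 12 with the largest change in each infection comparison and the 8 with the largest difference in each pair of organs. For each difference of infection effects they were the 6 with the lowest p. Unnamed gene models, pseudogenes, mitochondrial genes and the variable, joining and diversity segments of antigen receptors were left out of this rule. So were the constant genes of light chains and T cell receptors, such as Igkc and Trac, but not those of heavy chains, such as Ighg2c. Every gene named by rule had to pass with log2 FPKM of at least 3 in a group. In the infection comparisons the groups also had not to overlap, and where under 5 genes qualified, the 5 with the lowest p were taken instead. Members of lists and genes of known macrophage function were named beside them. Where a group had no read the fold is given as at least the value at a floor of 3 reads per library, and with 1 to 3 reads as a ratio with a 95% counting interval. The fold of other genes near 0 FPKM depends on the count added before the logarithm. On GRCm38, positions were found for 448 of 448 named genes, and 48058 of the 48440 genes were in the annotation.

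The method was tested on simulated data with 50 genes changed per fold between infected and uninfected liver, 13607 genes in the fit. A 2-fold rise was found for 13 of 50 genes and a 4-fold rise for 32 of 47 tested. A fall to 0.5 was found for 10 of 50 and a fall to 0.25 for 27 of 49 tested. Of the 91 calls 9 were false, and in the unchanged lung and spleen 0 genes were called. A list of 32 lysosome genes raised by log2 1 was called (camera adjusted p = 1.58e-46, and adjusted p = 4.18e-08 with an estimated correlation) and 0 of the 37 other lists were. The simulated genes were drawn independently of each other, so false calls of lists whose members are correlated could not show. In the deposited data the lysosome list stood at a median log2 of -0.22 in infected lung (camera adjusted p = 0.000146, and adjusted p = 0.406 with an estimated correlation).

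Libraries of a group correlated between 0.81 (infected spleen) and 0.918 (uninfected lung) across genes. Scaling was left as deposited. Under quantile scaling the median log2 change of all genes became -0.101 in infected against uninfected liver (0 as deposited), -0.132 in uninfected liver against lung (0.022 as deposited) and 0.146 in uninfected lung against spleen (0 as deposited). Alternatives to the filter, scaling, added count, weights, model and list test are given with their values in the closing section, as are results without each library. Parasite reads, splicing and single transcripts could not be studied from this table. A few genes are not reported here.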

Results

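RNA of sorted mouse macrophages, bright for the surface proteins F4/80 and MHC class II, was compared between uninfected mice and mice that had received red blood cells carrying the malaria parasite Plasmodium yoelii 35 days earlier. The series states that the parasite had been cleared by then. Liver, lung and spleen were each represented by 3 infected and 3 uninfected libraries, 18 in all. Each library held between 23670175 and 40362001 reads in genes, and between 15793 (infected spleen library 4) and 19320 genes were detected. Levels are given in FPKM (fragments scaled to gene length and library size) as mean ± standard deviation over the 3 libraries of a group, and changes as log2 fold change ± standard error, averaged over the libraries on the log2 scale. Genes were tested with limma, a linear model that shares variance information between genes, and each p-value was adjusted for the 13738 genes tested (Benjamini-Hochberg, limit 0.05). The labels do not say whether the libraries of a group come from separate animals, so the p-values measure the spread between these libraries, part of which may be technical. On the GRCm38 assembly Clec4f lies on chromosome 6 from 83644542 to 83656187, and Gpnmb on the same chromosome from 49036546 to 49070929. The other genes named most often lie at chromosome 9, 119901616 to 120069879 (Cx3cr1), chromosome 17, 34257689 to 34269419 (H2-Ab1) and chromosome 2, 129364570 to 129371139 (Il1b).

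The uninfected macrophages of each organ carried the genes known for that organ. Clec4f, a lectin of Kupffer cells (the resident macrophages of liver), stood at 8010 ± 449 FPKM in liver against 0.568 FPKM in lung, a log2 difference of 14.43 ± 0.66 (limma adjusted p = 2.08e-10, n = 3 per organ). Car4, a carbonic anhydrase of alveolar macrophages (those of the air spaces), stood at 475 ± 217 FPKM in lung against 0.0384 FPKM in liver (log2 -13.38 ± 1.41, limma adjusted p = 1.66e-06, n = 3 per organ). Itgad, an integrin chain of the macrophages of splenic red pulp, stood at 719 ± 62 FPKM in spleen against 0.383 ± 0.187 FPKM in lung (log2 -11 ± 1.6, limma adjusted p = 4.7e-05, n = 3 per organ). In all, 3655 genes differed at least 2-fold between liver and lung, 2093 between liver and spleen and 3650 between lung and spleen.

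The fixed gene lists gave the same division. Of the 17 Kupffer cell genes, 17 were higher in liver than in lung (17 adjusted over the list alone) and 11 were higher in liver than in spleen (13 over the list alone), among them Vsig4 and Timd4. Of the 23 alveolar macrophage genes, 21 were lower in liver than in lung (22 over the list alone) and 20 were higher in lung than in spleen (20 over the list alone), Siglecf and Car4 included. Of the 13 red pulp genes, 11 were lower in lung than in spleen (13 over the list alone), and 5 were lower and 1 higher in liver than in spleen (10 lower and 1 higher over the list alone). Spic, the transcription factor of red pulp macrophages, was lower in liver than in spleen by a log2 difference of -3.00 ± 0.75 (limma adjusted p = 0.00876, every liver library under every spleen library).

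The organs also differed in what the resting cells made. Of 36 genes induced by type I interferon, 34 were higher in liver than in lung (35 over the list alone; median log2 4.43, camera list test adjusted p = 1.04e-20), and 28 were lower in lung than in spleen (33 over the list alone; adjusted p = 1.24e-11, and adjusted p = 0.0862 with an estimated correlation). Of 21 genes of cholesterol synthesis, 15 were lower in liver than in lung (18 over the list alone; median log2 -1.73, adjusted p = 4.12e-09) and 14 were higher in lung than in spleen (16 over the list alone; median log2 1.44, adjusted p = 3.4e-07). MHC class II genes, which load antigen for helper T cells, were lowest in lung, where 10 of 12 were under the spleen level (10 lower and 1 higher over the list alone; median log2 -5.54, adjusted p = 1.73e-07).

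The largest differences between organs involved genes with almost no reads on one side. Cd209f had 48309 reads in uninfected liver and 2 in lung (ratio 21100, 95% interval 5840 to 174000), and Cd209g was higher in liver than in spleen at a ratio of 9990 (2770 to 82500). Lhfp, Bmp2 and Sema6a had no read in lung and were at least 2660-fold, 2300-fold and 969-fold higher in spleen, counting 3 reads per library as the floor. These intervals and floors treat every read as an independent count. They are too narrow where both mates of a pair were counted or where PCR copied a read. Markers of other cells followed the organs as well. All 17 hepatocyte genes were higher in liver than in lung and in spleen (17 over the list alone each time), with Alb at least 2320-fold above lung. All 13 red blood cell precursor genes were lower in liver and in lung than in spleen (13 over the list alone each time), and 12 of 13 lung epithelium genes were higher in lung than in spleen.

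In infected liver macrophages MHC class II genes and Gpnmb rose, while Cx3cr1 and the lectins Cd209f and Cd209g fell. H2-Ab1, a chain of MHC class II, rose from 444 ± 128 to 2390 ± 279 FPKM (log2 2.46 ± 0.33, limma adjusted p = 0.000571, n = 3 per group, every infected library above every uninfected one). Gpnmb, a lysosomal glycoprotein of lipid-laden macrophages, rose from 0.328 ± 0.253 to 66.0 ± 31.5 FPKM (log2 8.09 ± 1.15, limma adjusted p = 0.000911, n = 3 per group). Cx3cr1, the receptor for the chemokine fractalkine, fell from 246 ± 6.53 to 22 ± 6.09 FPKM (log2 -3.52 ± 0.68, limma adjusted p = 0.00781, n = 3 per group), and the lectin Cd209f fell from 237 ± 59 to 1.31 ± 1.27 FPKM (log2 -8.89 ± 1.51, limma adjusted p = 0.00334, n = 3 per group). In all 507 genes rose and 122 fell.

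Beside Gpnmb the rise in liver took in Atp6v0d2 (log2 5.10 ± 0.61, limma adjusted p = 0.000265), a subunit of the lysosomal proton pump. It also took in the scavenger receptors Olr1 (log2 3.95 ± 0.58, adjusted p = 0.00118) and Cd36 (2.45 ± 0.34, adjusted p = 0.000816), and the integrin chain Itgax (3.34 ± 0.21, adjusted p = 7.9e-07), with the 3 infected libraries above the 3 uninfected ones for each gene. Nos2, which makes nitric oxide, went from 2 to 627 reads (ratio 341, 95% interval 94 to 2820; limma adjusted p = 0.0187), and Cxcl9, an attractant of T cells, rose by log2 2.55 ± 0.47 (limma adjusted p = 0.00592). Cd209g fell with Cd209f (log2 -8.71 ± 1.36, limma adjusted p = 0.00187). So did the adaptor Dab2 (-1.54 ± 0.23, adjusted p = 0.00133) and the iron carrier Trf (-1.38 ± 0.19, adjusted p = 0.000828). Csf1r, the receptor for a macrophage growth factor, fell less (-0.77 ± 0.15, limma adjusted p = 0.00653), as did Adgre1, the gene of F4/80 (-0.63 ± 0.16, adjusted p = 0.0349).

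Grouped by list, 8 of 12 MHC class II genes rose in liver and none fell (9 over the list alone; median log2 1.79, camera adjusted p = 3.81e-12), H2-Aa and H2-Eb1 among them. Of the 23 alveolar macrophage genes, 5 rose and none fell (11 over the list alone; median log2 1.43, adjusted p = 1.98e-08), Itgax and Olr1 included. Siglecf, of the same list, stood at log2 0.35 ± 0.47 (limma adjusted p = 0.786). Of the 17 Kupffer cell genes none passed: Clec4f stood at 4710 ± 122 FPKM after infection (log2 -0.76 ± 0.66, limma adjusted p = 0.615) and Timd4 at log2 -0.44 ± 0.85 (adjusted p = 0.865). Of 20 genes of monocyte-derived macrophages, 8 rose, Ly6c2 among them, and 1 fell, Cx3cr1 (8 and 1 over the list alone; adjusted p = 4.29e-05, and adjusted p = 0.0749 with an estimated correlation). Of 43 genes of oxidative phosphorylation, 9 rose, Ndufv2 (log2 1.00 ± 0.20) among them, and none fell (29 over the list alone; median log2 0.54, adjusted p = 4.49e-14, and adjusted p = 0.133 with an estimated correlation).

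Markers of other leukocytes rose in the same infected liver libraries. Ighg2c, the constant part of an antibody heavy chain, went from 3 to 9730 reads (ratio 3530, 95% interval 1210 to 17100; limma adjusted p = 1.99e-05). Of 14 neutrophil genes, 8 rose, Elane (log2 9 ± 1.87) and Ltf (8.48 ± 1.76) among them. Over the list alone 11 rose (median log2 6.73, or 5.56 with genes of no read at their floor, camera adjusted p = 4.06e-09, and adjusted p = 0.0749 with an estimated correlation). Of 14 T cell genes 5 rose (11 over the list alone; adjusted p = 4.09e-09, and adjusted p = 0.164 with an estimated correlation), and Cd8a went from 0 to 665 reads, at least 75.1-fold. Of 17 dendritic cell genes 4 rose (6 over the list alone; adjusted p = 6.71e-05, and adjusted p = 0.0749 with an estimated correlation). Leaving out 1 library lowered the liver count of 629 to 353, 295 or 359 (infected libraries 2, 3 and 4) and to 345 or 344 (uninfected libraries 2 and 3). The share of rises also hung on scaling, with 507 up and 122 down as deposited, 396 and 173 after centring each library on its median, and 596 and 295 after quantile scaling, which shifted the median of all genes by log2 -0.101.

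**Figure D1:**
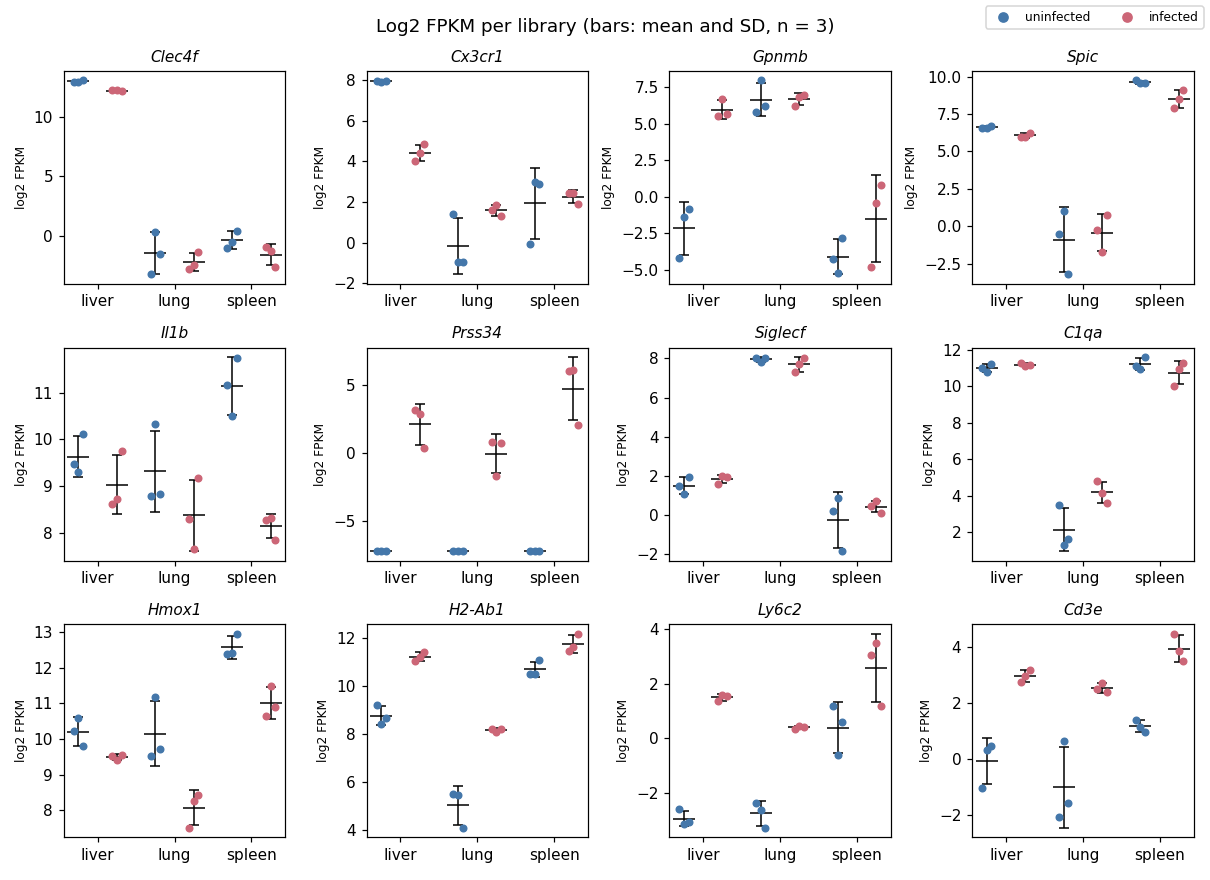
Level of 12 genes in each library (log2 FPKM), by organ, with bars for mean and standard deviation (n = 3 per group), blue for uninfected and red for infected. The genes were chosen after their values were seen.

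In infected lung macrophages, sorted like all groups as bright for MHC class II protein, RNA of MHC class II and of complement C1q rose. H2-Ab1 rose from 35.8 ± 16.1 to 285 ± 13.8 FPKM (log2 3.12 ± 0.33, limma adjusted p = 0.000112, n = 3 per group, every infected library above every uninfected one). C1qb, a chain of the complement starter C1q, rose by log2 2.67 ± 0.30 (limma adjusted p = 0.000162, n = 3 per group). Hmox1, the enzyme that breaks down heme, fell from 1310 ± 890 to 278 ± 84.8 FPKM (log2 -2.08 ± 0.39, limma adjusted p = 0.00716, n = 3 per group). Siglecf, a surface lectin of alveolar macrophages, stood at 212 ± 52.7 against 248 ± 17.9 FPKM (log2 -0.25 ± 0.47, limma adjusted p = 0.972), and Car4 at 271 ± 44.7 against 475 ± 217 FPKM (log2 -0.73 ± 1.41, adjusted p = 0.977). Here 327 genes rose and 4 fell. The other falls that passed were Abcb4, with 31 reads in uninfected and 1 in infected libraries (ratio 28.9, 95% interval 4.81 to 1180), and unnamed gene models. Among named genes the falls with the next lowest p did not pass, as for Ppan (log2 -0.62 ± 0.16, limma adjusted p = 0.0594) and the bacterial sensor Nod2 (-0.98 ± 0.27, adjusted p = 0.0747).

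Of the 12 MHC class II genes 9 rose in lung (9 over the list alone; median log2 3.06, camera adjusted p = 2.06e-20), and their regulator Ciita rose by log2 4.02 ± 0.82 (limma adjusted p = 0.0133). Of 15 genes of interstitial macrophages (those of the lung tissue outside the air spaces), 5 rose, C1qa (2.06 ± 0.45) among them (10 over the list alone; median log2 2.06, adjusted p = 4.25e-08). Of 20 complement genes 7 rose, C4b (log2 3.72) and Cd55 (3.78) among them (10 over the list alone; adjusted p = 9.4e-09). Of 30 genes induced by interferon gamma 6 rose (11 over the list alone; median log2 1.15, adjusted p = 2.04e-09), and of 36 induced by type I interferon 2 rose (3 over the list alone; median log2 0.30, adjusted p = 0.000707, and adjusted p = 0.406 with an estimated correlation). None of the 23 alveolar macrophage genes passed (median log2 -0.08, adjusted p = 0.476), although their median level was lower in each infected library (log2 7.61 to 7.88) than in any uninfected one (7.92 to 8.02).

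Genes of B cells, plasma cells and lung epithelium rose in the same infected lung libraries. Of 15 B cell genes 11 rose, Cd79b (log2 4.5 ± 0.59, limma adjusted p = 0.000401) and Cd79a (3.87 ± 0.46, adjusted p = 0.000259) among them (14 over the list alone; camera adjusted p = 2e-20). Of 10 plasma cell genes 6 rose, the antibody joining chain Jchain by log2 5.67 ± 1.2 (9 over the list alone; adjusted p = 3.03e-13). Of 13 lung epithelium genes 3 rose (10 over the list alone; median log2 3.73, adjusted p = 3.03e-13), and Scgb3a2, a secreted protein of airway cells, rose by log2 5.42 ± 0.96 (limma adjusted p = 0.00471). Of 17 dendritic cell genes 6 rose (8 over the list alone; adjusted p = 2.38e-07), Flt3 at least 23.1-fold from no read. B cells and dendritic cells make MHC class II themselves, and the table alone could not separate their part of its rise. The interstitial macrophage list, which holds C1qa and C1qb, and the lung epithelium list rose in the same libraries. Whether a larger share of such cells brought part of the rise of MHC class II or C1q was not tested. Under quantile scaling 137 genes passed in lung, 132 of them among the 331. With only the lung libraries fitted 58 passed, 44 of them among the 331.

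In infected spleen macrophages Il1b, Siglec1 and Hmox1 fell, while genes of granulocytes such as Prss34 rose. Il1b, which encodes an inflammatory cytokine, fell from 2390 ± 988 to 287 ± 49.1 FPKM (log2 -2.98 ± 0.46, limma adjusted p = 0.00251, n = 3 per group, every infected library under every uninfected one). Siglec1, a sialic acid receptor of macrophages, fell from 16.3 to 4.11 FPKM (log2 -2.01 ± 0.16, limma adjusted p = 1.61e-05, n = 3 per group), and Hmox1 from 6200 ± 1460 to 2120 ± 669 FPKM (log2 -1.57 ± 0.39, limma adjusted p = 0.0338, n = 3 per group). Prss34, a protease of basophils and mast cells, went from 0 to 5872 reads, at least 497-fold (limma adjusted p = 4.28e-05, n = 3 per group). In all 285 genes rose and 317 fell. These calls rest on a spread taken from all 6 groups. With only the spleen libraries fitted 56 genes passed, 23 up and 33 down, and 43 of them were among the 602 of the main fit.

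With Il1b fell Il1a (log2 -2.87 ± 0.52, limma adjusted p = 0.00669), the prostaglandin enzyme Ptgs2 (-2.70 ± 0.49, adjusted p = 0.00669) and Il12b (-3.66 ± 0.84, adjusted p = 0.0247), each lower in the 3 infected libraries than in any uninfected one. Of 28 inflammatory cytokine genes 6 fell and 1 rose (9 and 5 over the list alone; camera adjusted p = 0.0728 for the list as a whole). Of 28 immediate early genes, which answer within minutes to stimulation and to handling of tissue, 7 fell, Fosb (log2 -1.43 ± 0.18) among them (12 over the list alone; adjusted p = 0.000475, and adjusted p = 0.316 with an estimated correlation). Of the 13 red pulp genes 5 fell, Mrc1 (-0.83) and Trf (-0.88) among them (6 over the list alone; median log2 -0.88, adjusted p = 4.36e-05, and adjusted p = 0.181 with an estimated correlation). Spic stood at 387 ± 163 against 787 ± 58.2 FPKM (log2 -1.11 ± 0.75, limma adjusted p = 0.445). Its error is shared over all 6 groups, and in spleen every infected library lay under every uninfected one. Of 21 genes of heme and iron handling 4 fell (4 over the list alone, with 1 up; adjusted p = 0.00509, and adjusted p = 0.396 with an estimated correlation). Of the 12 MHC class II genes 2 rose, H2-DMb2 (log2 1.21 ± 0.23) and H2-DMb1 (1.09 ± 0.28). Over that list alone 6 rose (adjusted p = 0.00068, and adjusted p = 0.193 with an estimated correlation), and H2-Ab1 stood at log2 1.05 ± 0.33 (limma adjusted p = 0.0842).

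Of 14 neutrophil genes 8 rose in spleen, Mpo from 0.931 ± 0.913 to 86.2 ± 63 FPKM and Ngp by log2 7.76 (11 over the list alone; median log2 6.08, camera adjusted p = 6.43e-09, and adjusted p = 0.104 with an estimated correlation). Of 10 genes of eosinophils, basophils and mast cells 3 rose (8 over the list alone; adjusted p = 1.02e-05, and adjusted p = 0.0591 with an estimated correlation), and Epx went from 0 to 2744 reads, at least 235-fold. Rgs13 (log2 8.15 ± 1.87) and Nuggc (9.20 ± 1.88), genes of germinal center B cells, rose too (limma adjusted p = 0.0237 and 0.0129). Of 13 genes of red blood cell precursors 2 fell, the hemoglobin genes Hbb-bt (log2 -3.49 ± 0.89) and Hba-a2 (-3.18), whose near-identical copies share reads. Over the list alone 6 fell (median log2 -2.79, adjusted p = 4.36e-05, and adjusted p = 0.104 with an estimated correlation). Infected spleen library 4 lay apart, with 13 of the 14 neutrophil genes under both other infected libraries, and without it 915 genes passed in place of 602. Without infected library 2, uninfected library 1 or uninfected library 2 the count was 308, 276 or 290. After centring on the median 252 rose and 447 fell.

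Across organs 16 genes rose in all 3, where 0.25 would do so if the organs were independent. Among them were the antibody genes Ighg1, Ighg2b and Ighg2c, whose sequences are close enough to share reads, and the T cell receptor genes Cd3e and Trac. Others were the early activation antigen Cd69, Gpr183, a receptor for oxysterols, and the MHC class II chaperones H2-DMb1 and H2-DMb2. Ly6c2, a surface antigen of inflammatory monocytes, rose by log2 4.42 ± 0.60 in liver, 3.14 ± 0.60 in lung and 2.18 ± 0.60 in spleen (limma adjusted p = 0.000651, 0.00799 and 0.0497), although in spleen the libraries of the groups overlapped. Liver and lung shared 74 rises (12.1 expected if independent), liver and spleen 74 (10.5 expected) and lung and spleen 23 (6.8 expected). Liver and spleen shared 31 falls (2.8 expected), C2 and Trf among them, while liver and lung shared 0 falls (0 expected, as only 4 genes fell in lung) and lung and spleen 2 (0.1 expected). The same estimate of each gene's spread served the tests in all 3 organs. Calls can therefore coincide without a shared response, and the excess over these expected numbers cannot all be read as one. Opposite changes were called for 9 genes that rose in lung and fell in spleen and 0 the other way round. For 4 genes the rise was in liver and the fall in spleen, for 3 the reverse, and 1 gene fell in liver and rose in lung. An infected group lying wholly to one side of its uninfected group has a 10% chance for any gene of these group sizes, so separation alone was not counted as a change.

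**Figure D2:**
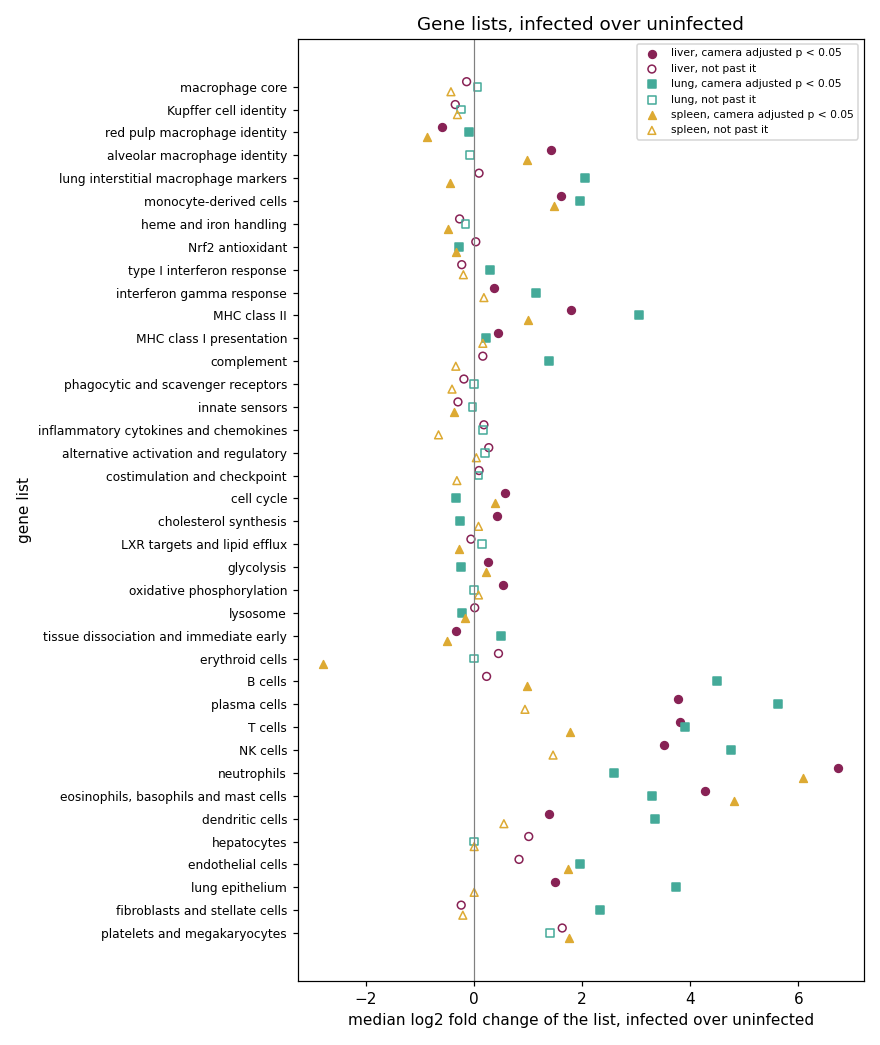
Median log2 fold change after infection of the 38 gene lists in each organ. Filled points have a camera adjusted p under 0.05.

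Testing the difference between organs set apart 135 genes between liver and lung, 85 between liver and spleen and 205 between lung and spleen. Itgax rose in liver by 3.37 ± 0.30 log2 units more than in lung and by 3.69 ± 0.30 more than in spleen (limma adjusted p = 4.91e-05 and 2.75e-05, n = 3 per group). Gpnmb rose by 8.07 ± 1.63 more in liver than in lung (limma adjusted p = 0.0277). It was already high in uninfected lung (log2 FPKM 5.78 to 7.94) and reached 5.5 to 6.68 in infected liver. Cx3cr1 changed by -5.29 ± 0.97 in liver relative to lung (limma adjusted p = 0.0148). Rnf128, a ubiquitin ligase, went from 0 to 332 reads in spleen, at least 31.8-fold, and did not pass in lung (limma adjusted p = 0.000262 for the difference). Chil3, a chitinase-like protein, rose in spleen by log2 5.19 ± 0.53. Cd274, an inhibitor of T cells, rose in liver (log2 1.15 ± 0.18) and fell in spleen (-1.27 ± 0.18), and Rsad2, an antiviral gene, rose in lung (1.54 ± 0.30) and fell in spleen (-2.13 ± 0.30).

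By list, the alveolar macrophage genes rose more in liver than in lung, 3 of 23 singly (5 over the list alone; median difference 1.64, camera adjusted p = 6.8e-08). The interstitial macrophage genes rose more in lung than in liver, 4 of 15 singly (7 over the list alone; adjusted p = 4.85e-07), and more in lung than in spleen, 3 of 15 singly (9 over the list alone; median difference 2.00, adjusted p = 2.73e-07). The organs started from unlike levels. For uninfected liver against lung the median log2 difference was -7.6 for the alveolar genes and 8.66 for the interstitial genes. For uninfected lung against spleen it was -5 for the interstitial genes. How far these start levels set the differences in rise was not tested. The MHC class II genes rose more in lung than in spleen, 4 of 12 singly (8 over the list alone; median difference 2.00, adjusted p = 1.62e-06, and adjusted p = 0.0851 with an estimated correlation), H2-Ab1 by 2.07 ± 0.46 (limma adjusted p = 0.0318). For liver against spleen no MHC class II gene passed singly (4 over the list alone; median difference 0.82, adjusted p = 0.00061, and adjusted p = 0.386 with an estimated correlation). The immediate early genes differed between lung and spleen, 8 of 28 singly (12 over the list alone; adjusted p = 4.75e-08, and adjusted p = 0.0855 with an estimated correlation). These counts moved with single libraries. Without infected liver library 3 or 4, infected lung library 3 or uninfected liver library 4 the 135 became 72, 87, 82 or 89. The 85 became 28, 46 or 36 without infected liver library 2, 3 or 4, 45 or 52 without uninfected liver library 2 or 3, 145 without infected spleen library 4 and 51 without uninfected spleen library 1. The 205 became 384 without infected spleen library 4 and 311 without uninfected lung library 3.

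**Figure D3:**
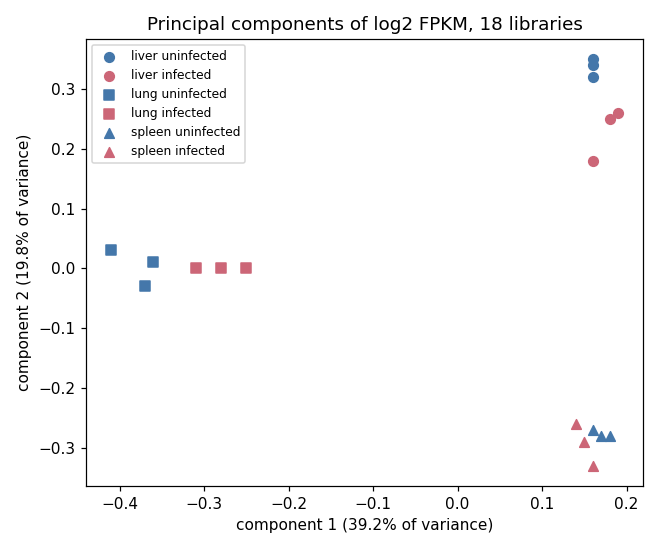
Position of the 18 libraries on components 1 (39.2% of variance) and 2 (19.8%) of the genes tested, blue for uninfected and red for infected.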

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

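The test of the difference between organs, fixed in advance, set apart 135, 85 and 205 genes for liver against lung, liver against spleen and lung against spleen. After the mean infection effect of both organs was taken out, 124, 81 and 199 genes passed, and among 100 splits of the 12 libraries only 1, the real one, gave as many each time (highest other 20, 10 and 12). For each comparison of 2 groups only 1 of the 10 possible splits, again the real one, gave as many genes, which is too few splits to exclude chance. The highest other split gave 3, 25 and 68 genes for infected liver, lung and spleen. For uninfected liver against lung, liver against spleen and lung against spleen it gave 4, 2 and 4.

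For liver against lung the genes set apart by that test were led by Itgax (3.37), Cd9 (3.77), Cd36 (3.51), Fabp5 (4.21), Hvcn1 (1.64) and Napsa (2.78), all given as log2 differences, which rose in liver and had adjusted p over 0.05 in lung. Cadm1 (-2.23), Rasgrp1 (-4.3), Tmem176b (-4.1), St3gal5 (-7.04) and Cd79b (-5.25) rose in lung and did not pass in liver. The size for St3gal5 is uncertain, as uninfected lung had 3 reads (ratio in lung 76.2, 95% interval 25.7 to 373). Cd209f (-14.04) fell in liver, by log2 -8.89, and the rest of its value comes from a change in lung that did not pass, over 2 reads in uninfected lung (ratio 29, 7.65 to 245).

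For liver against spleen the test set apart Itgax (3.69) and Glipr1 (1.86), which rose in liver and did not pass in spleen. Cd274 (2.42) and the survival genes Bcl2a1d (3.31), Bcl2a1a (4.58) and Bcl2a1b (2.94), near-identical copies that share reads, rose in liver and fell in spleen. Itgal (-2.14) and Dab2 (-2.67) fell in liver and rose in spleen. Rnf128 (-8.66), Camk1d (-1.44), Dok2 (-2.23) and Tnfrsf13b (-2.4) rose in spleen and did not pass in liver. Uninfected spleen had no read of Rnf128, so the size of its values here and below is set by the count added before the logarithm, and its rise in spleen is at least 31.8-fold.

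For lung against spleen it set apart Prnp (4.5), Lhfp (12.15) and Rsad2 (3.67), which rose in lung and fell in spleen, Siglec1 (2.07), which fell in spleen, and Cadm1 (2.56) and Ptpn22 (3.96), which rose in lung. Rnf128 (-9.16), Chil3 (-5.58), Itgal (-1.52), Anxa1 (-4.03), Spp1 (-3.81) and Dok2 (-2.01) rose in spleen and did not pass in lung. The size for Lhfp is likewise set by the added count, since uninfected lung had no read, and its rise in lung is at least 17.5-fold.

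The tests of B cells and dendritic cells below were chosen after the rise of MHC class II was seen, and their marker genes and bounds were changed after the values of earlier sets were seen. B cells among the sorted cells may bring MHC class II, but at the ratio seen in lung (49.8 FPKM of MHC class II per FPKM of marker) their 4 markers would bring -2.47% of the liver rise (highest over libraries 5.81%). An earlier set of 3 markers gave 6.66% (highest 24.1%). The original 12 changed in liver by -26.3 FPKM (-53.4 to -8.21 over libraries), against a rise of MHC class II of 8700 FPKM. In lung those 12 changed by -16.4 to 49.4 FPKM over libraries, so their ratio there could not be bounded. By the sets of 4 and 3 markers B cells do not account for most of the liver rise. This holds only as far as the markers track B cells in liver, where some of them fell. Dendritic cells might bring 57.5% of the liver rise (10.4 to 309% over libraries) by 6 markers and 45.8% with no bound by the original 17, at 403 FPKM per FPKM of marker in lung, so this explanation stays open. A rise within the macrophages stays open too, and in lung neither kind of cell could be bounded. Interstitial macrophages and epithelium were not tested as sources in lung. Sorting with the dendritic cell marker Zbtb46 would test the dendritic cells.

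The tests of neutrophils and of depth were chosen after the granulocyte genes were seen to rise. A differing share of neutrophils among the sorted cells could explain the rise in spleen, since 13 of the 14 neutrophil genes were lower in infected spleen library 4 than in both other infected libraries, against 38.2% of all genes. The median of the list was log2 4.97, 5.39 and 1.04 in infected libraries 2, 3 and 4 and at most -0.69 in uninfected ones. Deeper infected libraries do not account for the markers in liver or lung, where the ratio of reads, infected to uninfected, was 0.919 and 0.883. In spleen the ratio was 1.016, which leaves a small effect of depth open.

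The test of sex was chosen after Y-linked reads were seen in 3 uninfected libraries, liver library 3 (10532 reads), lung library 2 (4707) and spleen library 1 (6113), while every other library held at most 10. Animals of another sex in the uninfected groups, or pooled ones, as Xist reads in that lung library (5973) and that spleen library (5720) might mean, could have shifted the comparisons. Without those libraries the fold changes of the genes called kept a median ratio of 0.991 in liver, 1 in lung and 0.988 in spleen (lower quartiles 0.914, 0.854 and 0.914). The sizes of most of these changes thus did not rest on those libraries. The genes had been called with those libraries in, which favors genes with little spread, so the ratio could not exclude an effect of sex. Fewer genes passed without those libraries, 299, 285 and 179.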

How the results depend on the processing

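Most results that passed in the main fit kept their direction under other settings, while the numbers of genes past the threshold moved. Unless a reason is given the cause was not tested. Voom on the recovered reads and the settings without the libraries holding Y-linked reads and without infected spleen library 4 were added after the data were seen. Single genes and lists were compared only where they passed in the main fit, mostly on the same libraries, so reversals were unlikely from the start. Of the values of such genes 5434 kept their sign and still passed, 1572 kept it but did not pass, and 0 reversed. Of the values of such lists 2223 kept their direction and still passed, 368 kept it but did not pass, and 2 reversed. The reversed ones were the lysosome list in spleen under quantile scaling (adjusted p = 0.302) and the endothelial list for liver against lung under log2 of FPKM plus 1 (adjusted p = 0.184), and neither passed.

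With library weights, which give noisy libraries less say, more genes passed, namely 1375 in liver, 548 in lung, 1677 in spleen and 302, 302 and 783 for the differences liver against lung, liver against spleen and lung against spleen. With log2 of FPKM plus 1 lung had 201, spleen 1057, liver against spleen 251 and lung against spleen 370, and with FPKM plus 0.1 liver against spleen had 144. Quantile scaling left 137 in lung and 117 for lung against spleen. Voom on the recovered reads gave 139 in lung, 80 for liver against lung and 139 for liver against spleen. Fitting only the groups compared gave 58 in lung, 56 in spleen, 217 for liver against lung and 113 for lung against spleen. Such a fit has fewer residual degrees of freedom and takes its spread from those groups alone. As some counts rose and others fell, fewer degrees of freedom are not given as the reason. In liver that fit gave 729 genes (496 up and 233 down), 396 of them among the 629 of the main fit. The stricter filter tested fewer genes and left 188 in lung and 1989, 1203 and 2069 between uninfected organs. Without the libraries holding Y-linked reads 299 passed in liver, 179 in spleen and 37 for liver against spleen.

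Treating libraries of the same number as a block left 235 in spleen and 55, 18 and 75 for the differences liver against lung, liver against spleen and lung against spleen. The main fit was set without a block in advance, and the labels do not state such blocks. The deviations of libraries of the same number correlated at most at 0.068.

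The number of lists called fell with the correlation estimated from the data, to 2, 12 and 0 in liver, lung and spleen, to 2, 0 and 1 for the differences and to 8, 3 and 10 between uninfected organs, because a larger correlation widens the error of each list by construction. Fry called 14 in lung, 12 in spleen and 7, 4 and 12 for the differences. With the stricter filter 5 were called for liver against spleen.

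Leaving out each library in turn gave 295 to 475 genes in liver, 222 to 456 in lung, 276 to 915 in spleen, 72 to 175 for liver against lung, 28 to 145 for liver against spleen and 144 to 384 for lung against spleen. Between uninfected organs it gave 3307 to 3468, 1746 to 1936 and 3368 to 3564. The lists called ranged from 18 to 19, 22 to 25 and 15 to 23 in the infected organs, 14 to 21, 5 to 11 and 17 to 26 for the differences, and 25 to 27, 17 to 21 and 24 to 28 between uninfected organs. The 915 came without infected spleen library 4, which weighed 0.25 in the weighted fit, and without it in any fit 919 genes passed in liver.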

Other observations

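Single genes that act on T cells rose in infected liver, Pdcd1lg2, a ligand of the inhibitory receptor PD-1, by log2 3.83 and Ccl22, which draws regulatory T cells and is also a dendritic cell marker, by 5.48. The 17 genes of costimulation and checkpoints did not pass as a list, with 5 up and 1 down (5 and 2 over the list alone; median log2 0.09, camera adjusted p = 0.201). The cytokine Osm rose by log2 3.37 ± 0.40 (limma adjusted p = 0.000265, every infected library above every uninfected one), and the endosome protein Cd63 by 2.86. In lung Serping1, the inhibitor of the complement protease C1, rose by log2 6.07 beside C4b, and Il12b by 5.94, although it fell in spleen, a difference of 9.60 ± 1.19 (limma adjusted p = 0.00068). In spleen Ear1, a gene named for eosinophils but on the alveolar macrophage list, went from 2 to 396 reads (ratio 165, 95% interval 45.5 to 1370). There the lysozyme Lyz2 rose by log2 2.54, while Mertk, which clears dying cells, fell (log2 -1.05).

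Whether a smaller share of Kupffer cells lay behind the fall of Cx3cr1, Cd209f and Cd209g in liver was tested after the values were seen. None of these genes is on the Kupffer cell list, and Cx3cr1 is on the list of monocyte-derived macrophages. The test takes Kupffer cells as their source. If a smaller share of Kupffer cells explained the fall of Cx3cr1, Cd209f and Cd209g, then Clec4f, Timd4 and Vsig4 should fall as far. Between any infected and any uninfected liver library their largest fall was log2 -0.89, and the smallest fall of Cx3cr1 was -3.08, which argues against a smaller share as the whole cause. By the earlier version of the test, 2 standard errors of the shared fit, Vsig4 could have fallen to -3.28, Timd4 to -2.13 and Clec4f to -2.08, so the explanation was not excluded for Cx3cr1. Cd209f and Cd209g fell beyond those limits, with smallest falls between libraries of -6.07 and -7.59. For these 2 genes both versions argue against a smaller share as the whole cause. Loss of only those sorted cells that carry these genes, whether Kupffer cells or other macrophages, stays open, since Clec4f, Timd4 and Vsig4 would not show it. For Cx3cr1, staining for CLEC4F and CX3CR1 on the same cells would tell.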
